A study of Mus musculus with 6 samples.

How the data were processed

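RNA sequencing was performed on bone marrow-derived macrophages, which are macrophages grown in culture from mouse bone marrow, after 6 h of stimulation with lipopolysaccharide (LPS), a cell wall component of Gram-negative bacteria. Per the labels, 3 libraries came from C57BL/6 mice with floxed Xbp1 alleles and no deletion (Xbp1FL/FL, called WT here) and 3 from mice whose Xbp1 is deleted in myeloid cells (Xbp1M-KO, called KO here). All 6 libraries were exposed to LPS, so the LPS response itself was not analysed here. The labels do not say whether the 3 libraries of a genotype came from separate animals, so p-values measure the spread between these libraries, which may be technical. Libraries were built from total RNA with the NEBNext Ultra kit, per the labels' protocols. How RNA was selected, whether strand was kept and how reads were assigned to genes are not given in the sources used here.

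The authors deposited a single table of 54660 gene rows, of which 54532 carry an Ensembl mouse identifier and 128 another kind of identifier and no gene name. The 128 rows held between 0.0427% and 0.0502% of a library's counts and were kept. The deposited counts are whole numbers of reads per gene, not normalized, per the file headers and the values. The deposited FPKM values, which are fragments scaled by gene length and library total, use a library total that the authors scaled by a single factor per library. Those scaled totals are proportional to the median-ratio size factors of DESeq2 computed here from the deposited counts, with a highest to lowest ratio of 1.00. The deposited signal columns hold the authors' mean normalized counts of each genotype and were not tested. The authors also deposited a log2 fold change per gene and its p-value and adjusted p-value, and the tool behind them is not named in the headers. Of the 20680 genes with such values, 99.995% had a deposited log2 fold change within 0.001 of that from a DESeq2 fit with genotype as the term, and 75.2% a log10 p within 0.001. Bowtie 0.12.2 and the builds mm8 and mm10 are listed in the submitters' processing notes with no role for either build. Coordinates in the deposited table were compared with the GENCODE vM21 annotation of the mm10 assembly. Of 54495 Ensembl identifiers found there, 98.3% had an identical chromosome, start and end, and positions are given on that assembly.

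Library totals were 37652501, 34488573 and 32584064 counts for WT replicates 1 to 3 and 31976748, 35001455 and 42448058 for KO replicates 1 to 3. At these depths 3 counts equal between 0.0707 and 0.0938 CPM, the count scaled to a common library size. Pairs of libraries of the same genotype differed by more than sampling noise, with a chi-square per degree of freedom between 2.87 and 6.70 over genes, so none was counted as a duplicate.

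Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test on the deposited counts of all 6 libraries with genotype as the term, TMM scaling and the default expression filter, which left 13080 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Positive log2 fold changes mean higher in KO. The standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM with the SD over 3 libraries. On simulated counts for 13080 genes with 200 changed genes in the KO against WT design, the test recovered 82% of 1.5-fold and 98% of 2-fold changes and called 12 unchanged genes.

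Gene lists, 31 in number and fixed before the data were examined together with the tests and most alternatives, hold 586 genes, of which 514 passed the filter. They cover endoplasmic reticulum stress, innate immune signalling, fibrosis, metabolism, antigen presentation, proliferation, macrophage identity and markers of other cell types. The 27 lists with at least 5 tested members were tested with camera from limma 3.58.1 with a preset inter-gene correlation of 0.01, two-sided, and Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated per list and fry were run beside it. Members of a list were counted as risen or fallen from the adjusted p over all genes, and again adjusted over the list alone. Camera was also run on data simulated with independent genes and no GC or length trend. There it called 4 of 4 lists shifted by 0.3 on the log2 scale and 0 of the unshifted lists. Estimated correlations of the real lists reached 0.271, so these counts give no error rate for them.

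Genes named in the text follow a rule set before the data were examined. It takes Xbp1, the 10 highest and 10 lowest log2 fold changes among called genes with separated groups and a mean of at least 1 CPM, up to 2 called members with the largest change from each list, and Cgas, Sting1, Nlrp3, Bnip3, Tnf, Il1b, Il6 and Ifnb1 whatever their result. Genes named outside this rule are marked as chosen after their values were seen. A gene that the rule selects is not reported here. Of the tested genes, 2178 have a near-identical copy, defined with BLAST 2.17.0 as at least 95% identity over at least 200 bases between longest transcripts. Counts of such genes are uncertain where reads could be split between copies.

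Alternatives planned in advance were no expression filter, a mean of at least 5 CPM, other scalings, DESeq2 1.42.0, a replicate block, leaving out each library, stricter thresholds and other list tests. Further analyses were added after the data were seen. The main one removed a smooth trend in GC content and gene length from each library, fitted with mgcv 1.9.3 and entered as an offset in edgeR. In counts simulated for 13080 genes with such a trend, the uncorrected test called 3955 unchanged genes and the corrected test 14. The simulated trend was built from the same GC contents and lengths that the correction used. It does not show how the correction performs where those differ from the sequenced mRNA. The others used limma on log2(FPKM + 1), left out genes with near-identical copies, tested transcription factor families from the deposited annotation, compared chemokines with stromal markers, ran camera with an estimated correlation under other filters and scalings, took the share of Lyz1 in the reads of Lyz1 and Lyz2 and the sum of both, and summed the counts of Gapdh and of Sumo2 with those of their copies. A change of pseudocount does not apply to a test on counts.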

Results

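The transcriptomes of LPS-stimulated macrophages were compared between floxed control mice and mice lacking Xbp1 in myeloid cells. XBP1 is a transcription factor of the unfolded protein response. The study's title poses the question of whether XBP1 acts on STING signalling in macrophages during liver fibrosis. Each genotype was represented by 3 libraries of between 31976748 and 42448058 counts, all collected 6 h after LPS.

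Xbp1 (ENSMUSG00000020484, chromosome 11, 5520659 to 5525893 on mm10) was lower in every KO library than in every WT library. Its level was 91.2, 88.2 and 87.5 CPM in WT replicates 1 to 3 and 66.3, 65.5 and 65.6 CPM in KO replicates 1 to 3. The log2 fold change was -0.44 (SE 0.0363, edgeR adjusted p = 2.38e-08), and the KO mean of 65.8 CPM was 0.740 times the WT mean of 89.0 CPM. The authors' deposited table gives -0.43 for this gene. Gene counts include exons that may lie outside the deleted part, and which exon is floxed is not given in the sources used here.

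Of 13080 genes tested, 8019 were called, 4115 higher and 3904 lower in KO, and most changes were small. A change of at least 2-fold was found for 377 higher and 521 lower genes, while 61.1% of the called genes changed by less than 1.5-fold. The groups did not overlap for 65.9% of tested genes, against 10% expected by chance for 3 against 3 libraries. Scaling by library totals alone shifted the median of all genes by 0.11 on the log2 scale and made 63.4% of calls higher in KO, against 51.3% with TMM. Log2 fold changes also followed GC content and gene length, a trend described in the last paragraphs. Of the 8019 calls, 5790 kept their direction as calls once that trend was removed and 255 became calls in the opposite direction.

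Among the genes with the largest falls were Il10, which encodes an anti-inflammatory cytokine, and Ccl7, a monocyte chemoattractant. Il10 fell from 104.9 ± 3.87 to 19.5 ± 0.115 CPM (SD, n = 3 each; log2 fold change -2.43, SE 0.0434, edgeR adjusted p = 4.43e-16). Ccl7 fell from 662 ± 30.2 to 140.4 ± 5.63 CPM (log2 fold change -2.24). Casp12, Angpt1, Gm18445, Pcolce2, Plscr2, Gm6634 and Hebp2 fell by between 1.83 and 2.27 on the log2 scale, from WT means of 1.63 to 6.56 CPM, and the values of Gm18445 and Gm6634 were -1.31 and -1.21 after removal of the trend. Sumo2 had the lowest value, -2.53, but has 9 near-identical copies, and the summed counts of the gene and its copies changed by -0.68 (SE 0.0634, edgeR adjusted p = 7.69e-08). The largest rises were those of Lyz1, a lysozyme gene, at 2.47 (SE 0.0634, edgeR adjusted p = 4.34e-14), and Arrb1, which encodes beta-arrestin 1, at 2.06. Spn, the gene of the surface sialoglycoprotein CD43, rose from 5.72 ± 0.404 to 20.3 ± 1.81 CPM. The remaining genes among the 10 highest, 2610507I01Rik, Foxred2, Draxin, 6430548M08Rik, Tbc1d8, Bmf and Trerf1, rose by between 1.72 and 1.86 from WT means of 0.513 to 1.41 CPM.

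**Figure D1:**
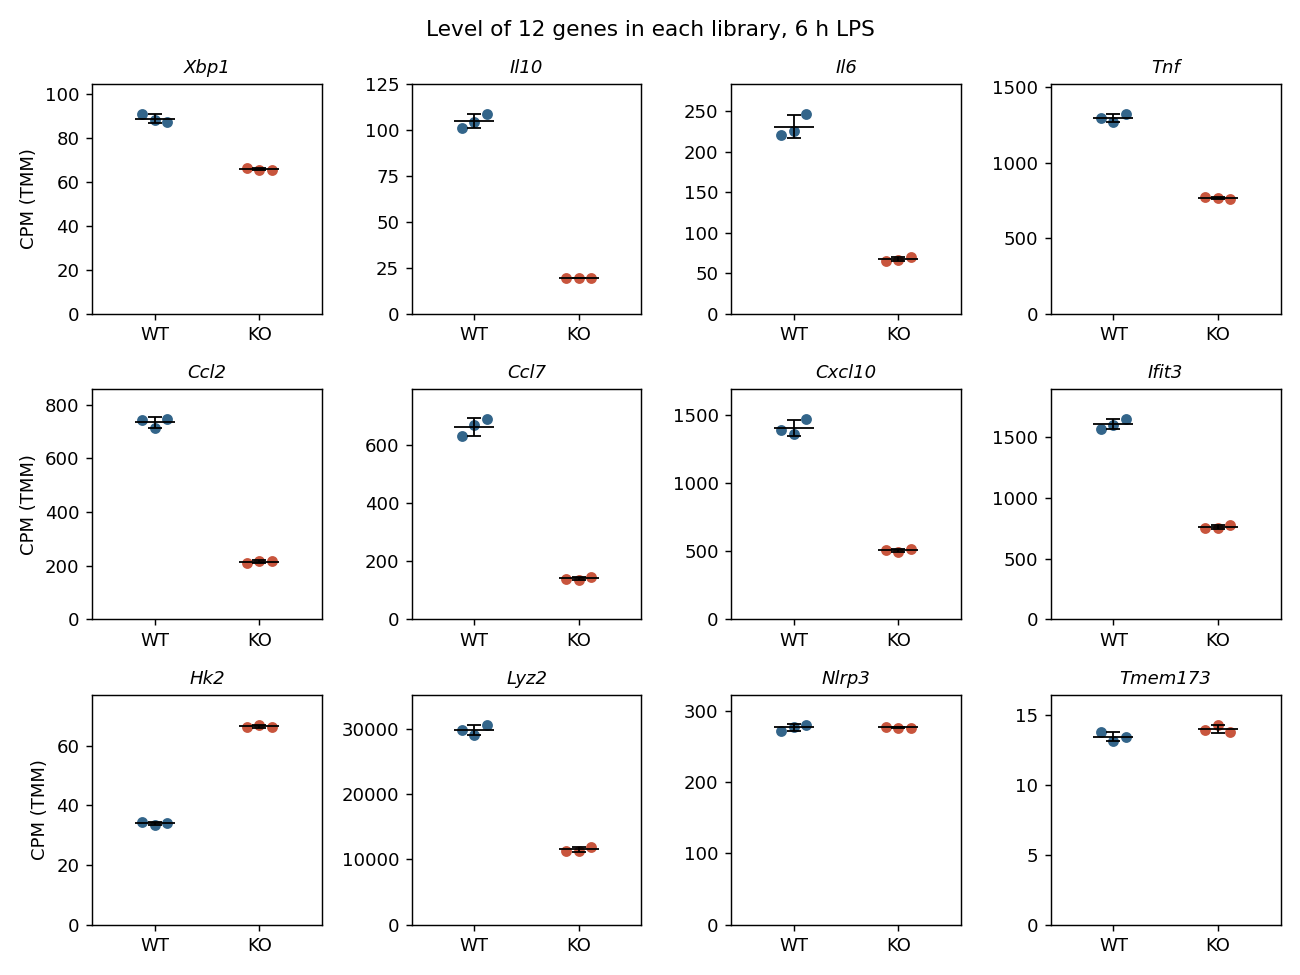
Each panel plots the TMM-scaled level in CPM (vertical axis, from 0) of a gene in the 3 WT and 3 KO libraries, with points for libraries and black bars for the mean and SD. Il10, Il6, Tnf, Ccl2, Ccl7, Cxcl10, Ifit3 and Lyz2 are lower in all KO libraries and Hk2 is higher, while Nlrp3 averages 277 CPM in both genotypes.

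Chemokine transcripts were lower in KO almost throughout. Of 16 measured chemokines 15 fell and 1 rose, the same counts when adjusted over the list alone, with a median log2 fold change of -1.03. Ccl2, which draws CCR2-bearing monocytes, fell from 734 ± 18.8 to 214 ± 5.25 CPM (log2 fold change -1.78, SE 0.0323, edgeR adjusted p = 4.43e-16). The member that rose was Ccl5, by 0.11, named after its values were seen. As a list the chemokines were called lower by camera (adjusted p = 7.07e-11), but not with an estimated correlation (adjusted p = 0.146). Removal of the GC and length trend reduced the median to -0.64. Stromal cell markers were also lower in KO, with a median of -0.53.

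Cytokines and feedback genes induced by LPS fell on balance, with some members moving the other way. Of 24 measured members 15 fell and 7 rose, and these counts did not change when adjusted over the list alone. Il6 fell by 1.78 (SE 0.0448, edgeR adjusted p = 4.32e-14) and Tnf by 0.76 (SE 0.0265, edgeR adjusted p = 7.55e-13) on the log2 scale. Csf2 was near the detection limit, with 54 counts over the WT libraries and 17 over the KO libraries, a ratio of 3.59 WT over KO (95% exact interval 2.05 to 6.61, counting error only). Its counts per library were 16 to 20 in WT and 3 to 8 in KO, so it likely passed the filter through WT, which favours a fall. Il1b changed by -0.31 (edgeR adjusted p = 2.41e-08). With the trend removed, Il1b was no longer called, at -0.05 (edgeR adjusted p = 0.0985), and with library totals as the scaling it was -0.20. These cytokines and feedback genes were called lower by camera (adjusted p = 0.00522), but not with an estimated correlation (adjusted p = 0.215).

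Interferon-stimulated genes, which are transcribed in response to type I interferon, were mostly lower in KO. Of 40 members 32 fell, 3 rose and 5 did not pass the test, and adjusted over the list alone 32 fell and 4 rose. Cxcl10 fell from 1406 ± 58.2 to 507 ± 12.5 CPM (log2 fold change -1.47) and Ifit3 by 1.08 on the log2 scale, although Ifit3 has a near-identical copy. The list median was -0.43, and -0.42 after removal of the trend. By camera the interferon-stimulated genes were lower (adjusted p = 9.30e-11), but not with an estimated correlation (adjusted p = 0.189).

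The genes of the cGAS-STING pathway itself, which senses cytosolic DNA, moved in both directions. Of 19 measured members 9 rose and 7 fell, the same counts adjusted over the list alone, and camera made no call (adjusted p = 0.933). After removal of the trend 6 rose and 9 fell. Ifnb1, which encodes interferon beta, fell by 1.00 (SE 0.170, edgeR adjusted p = 7.57e-05), and its change was -0.40 after removal of the trend. Trim32, a ubiquitin ligase gene, rose by 0.98. Sting1, listed as Tmem173, had 13.4 ± 0.2997 CPM in WT and 14.0 ± 0.276 CPM in KO (log2 fold change 0.06, SE 0.0643, edgeR adjusted p = 0.464). Cgas, listed as Mb21d1, had a log2 fold change of 0.20 (SE 0.143, edgeR adjusted p = 0.233). Without WT replicate 3 that value was 0.43 (edgeR adjusted p = 0.00427), and with library totals as the scaling Tmem173 was called at 0.17 (edgeR adjusted p = 0.0305).

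Profibrotic mediators and matrix remodelling genes were mostly lower in KO. Of 22 measured members 13 fell, 5 rose and 4 did not pass, with no difference when adjusted over the list alone, and the median was -0.59. Mmp12, the macrophage metalloelastase, fell from 129 ± 1.57 to 51.1 ± 1.26 CPM and Timp1, a metalloproteinase inhibitor, from 293 ± 10.1 to 132 ± 1.69 CPM. Camera called the list lower (adjusted p = 0.00207), but not with an estimated correlation (adjusted p = 0.146), although that estimate, -0.023, lay below the preset correlation. Markers of stromal cells and fibroblasts fell beside it, 9 of 13 measured members falling and 1 rising, also when adjusted over the list alone. Acta2, a smooth muscle actin, fell by 1.20 and Cxcl12 by 1.02 on the log2 scale. Camera called the stromal list lower (adjusted p = 9.09e-04), but not with an estimated correlation (adjusted p = 0.177), and its median moved from -0.53 to -0.83 after removal of the trend.

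The endoplasmic reticulum lists were not called in the main test. Of 40 genes of XBP1-linked secretion and ER-associated degradation 19 fell and 11 rose, also when adjusted over the list alone (median -0.10, camera adjusted p = 0.126). With library totals as the scaling the median was 0.02, and 16 fell and 14 rose. After removal of the trend 15 fell and 8 rose. Without genes that have near-identical copies camera called this list lower (adjusted p = 0.0442), but not with an estimated correlation (adjusted p = 0.198). Fkbp11, a peptidyl-prolyl isomerase of the secretory pathway, fell by 1.11 (SE 0.173, edgeR adjusted p = 3.25e-05). Srp54b, a signal recognition particle gene with near-identical copies, had -1.05 (edgeR adjusted p = 0.0230), but -0.35 (edgeR adjusted p = 0.380) without WT replicate 1 and -0.89 (edgeR adjusted p = 0.0856) without KO replicate 1. With the trend removed it was -0.90 (edgeR adjusted p = 0.0517). ER chaperones split into 8 that rose and 7 that fell of 20 (9 and 7 adjusted over the list alone; camera adjusted p = 0.933), with Manf at -0.43 and Ero1a, listed as Ero1l, at 0.46. In the PERK-ATF4-CHOP branch 13 of 22 fell and 4 rose, also adjusted over the list alone (median -0.19, and -0.07 with library totals as the scaling, where 9 fell and 5 rose; camera adjusted p = 0.0850). Wars fell by 0.57 and Sesn2 rose by 1.05. With the trend removed camera called this branch lower (adjusted p = 0.00747), but not with an estimated correlation (adjusted p = 0.0940), and with no expression filter the adjusted p of these camera tests was 0.0412 and 0.213. Substrates of IRE1-dependent RNA decay comprised 5 that fell and 3 that rose of 12, also adjusted over the list alone (camera adjusted p = 0.525), with Col6a1 at -0.86 and Sparc at -0.61.

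Inflammasome and pyroptosis genes gave no list call (camera adjusted p = 0.0919), with 7 of 15 falling and 2 rising, also when adjusted over the list alone. The median was -0.02. With library totals as the scaling the median was 0.10, and 7 rose and 6 fell. Camera called this list lower with no expression filter (adjusted p = 0.0404) and without genes that have near-identical copies (adjusted p = 0.0293), but in neither case with an estimated correlation (adjusted p = 0.158 and 0.254). Casp1 and Casp4, inflammatory caspase genes, fell by 0.94 and 0.90 on the log2 scale, and their values were -0.37 and -0.51 after removal of the trend. Both lie next to Casp12 on chromosome 9, between 5298517 and 5373032. Nlrp3 had a log2 fold change of 0.00 (SE 0.0307, edgeR adjusted p = 0.984), and -0.15 (edgeR adjusted p = 1.41e-04) once the trend was removed. With library totals as the scaling it was 0.12 (edgeR adjusted p = 0.00374). Alternative activation genes had 4 that rose and 1 that fell of 9 (3 and 1 adjusted over the list alone; camera adjusted p = 0.422), but 1 that rose and 4 that fell after removal of the trend, with Chil3 at 0.77 and the mannose receptor gene Mrc1 at -0.79.

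Glycolysis and hypoxia genes were higher in KO. Of 24 members 19 rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 0.39. Hk2, which encodes a hexokinase, rose from 34.0 ± 0.503 to 66.5 ± 0.463 CPM and Egln3, an oxygen-sensing prolyl hydroxylase gene, from 3.69 ± 0.251 to 7.73 ± 0.367 CPM. Camera called the list higher (adjusted p = 1.75e-07), but not with an estimated correlation (adjusted p = 0.146), and the median was 0.25 after removal of the trend. Near-identical copies exist for 9 of the 24 members. Without such genes camera called the list higher (adjusted p = 6.40e-04), but not with an estimated correlation (adjusted p = 0.153). Bnip3, a mitophagy receptor gene that also belongs to this list, rose by 0.27 (SE 0.0447, edgeR adjusted p = 6.03e-05) and by 0.69 after removal of the trend. It has 3 near-identical copies. Mitophagy and autophagy genes as a list moved both ways, 8 rising and 11 falling of 22, also adjusted over the list alone (camera adjusted p = 0.690), and 11 rising and 7 falling with library totals as the scaling. Ulk1 was at 0.92, and at 0.52 after removal of the trend.

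Respiratory chain transcripts were lower in KO. Of 13 mitochondrially encoded genes 12 fell and none rose, also when adjusted over the list alone, with a median of -0.96 and mt-Cytb at -1.14 (SE 0.0369, edgeR adjusted p = 3.66e-13), or -0.43 after removal of the trend. Their share of all counts was between 1.01% and 1.09% in WT libraries and between 0.654% and 0.679% in KO libraries. Near-identical copies exist for 8 of these 13 genes, whose counts are uncertain to that extent. Camera called this list lower (adjusted p = 1.05e-07), but not with an estimated correlation (adjusted p = 0.146). After removal of the trend its median was -0.15 and the camera call was lost (adjusted p = 0.0668). Of 25 nuclear respiratory chain genes 19 fell and 2 rose (20 and 2 adjusted over the list alone), with a median of -0.26, and of -0.14 with library totals as the scaling. Ndufa4 fell by 0.78 on the log2 scale, and its value was -0.16 after removal of the trend. Ndufa1 changed by -0.57, and by -0.04 (edgeR adjusted p = 0.460) after removal of the trend. Camera called the nuclear list lower (adjusted p = 9.56e-06), but not with an estimated correlation (adjusted p = 0.146). After removal of the trend the nuclear list had a median of -0.20, with 19 that fell and 3 that rose, and camera called it lower (adjusted p = 1.24e-04), but not with an estimated correlation (adjusted p = 0.0695).

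All 25 cytosolic ribosomal protein genes measured fell, also when adjusted over the list alone, with a median of -0.49. With library totals as the scaling 24 of them fell. Rpl10a fell from 515 ± 4.79 to 310 ± 2.93 CPM and Rpl3 from 526 ± 6.73 to 326 ± 4.87 CPM. Camera called the list lower (adjusted p = 2.89e-14), but not with an estimated correlation (adjusted p = 0.146). Near-identical copies exist for 21 of the 25 genes, and their counts are uncertain to that extent.

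Macrophage identity genes were not called as a list, with 12 of 20 rising and 6 falling, also adjusted over the list alone (camera adjusted p = 0.219). Lyz2, the macrophage lysozyme gene, fell from 29831 ± 761 to 11515 ± 348 CPM (log2 fold change -1.37, SE 0.0229, edgeR adjusted p = 4.43e-16). It lies beside Lyz1 on chromosome 10 and is its near-identical copy. Cx3cr1, the fractalkine receptor gene, rose by 0.87. Measured neutrophil markers were higher in KO, 9 of 10 members rising and 1 falling, also adjusted over the list alone, with a median of 0.74. Of the 15 listed, Ly6g, Mpo, Cxcr2, Retnlg and Ctsg averaged 0.0604 to 0.245 CPM and did not pass the filter. The granule protease genes Elane and Prtn3 were near the detection limit. Their counts per library were 1 to 4 and 5 to 8 in WT, and 12 to 27 and 14 to 28 in KO. Both thus likely passed the filter through KO, which favours a rise. Elane had 8 counts over the WT libraries and 56 over the KO libraries, a ratio of 6.19 (95% exact interval 2.93 to 15.03), and Prtn3 had 18 and 66, a ratio of 3.24 (1.90 to 5.80), both for counting error only. Camera called the neutrophil list higher (adjusted p = 0.00436), but not with an estimated correlation (adjusted p = 0.260). Lists of B, T and NK, mast and erythroid cells had 3, 2, 3 and 1 measured members and were not tested. Among these, Blnk was at 0.27, Lck at -0.85, Mcpt8 at -1.24 and Tfrc at 0.29, the last at 0.50 after removal of the trend. Cd4 was at 0.69 (edgeR adjusted p = 0.0173), a call lost without KO replicate 3 (0.62, edgeR adjusted p = 0.0728) and with the trend removed (0.50, edgeR adjusted p = 0.0790). Hdc was at -0.15 (edgeR adjusted p = 0.00886), a call lost without KO replicate 1 (-0.11, edgeR adjusted p = 0.0681) and with library totals as the scaling (-0.03, edgeR adjusted p = 0.570). With the trend removed Hdc was at -0.30.

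**Figure D2:**
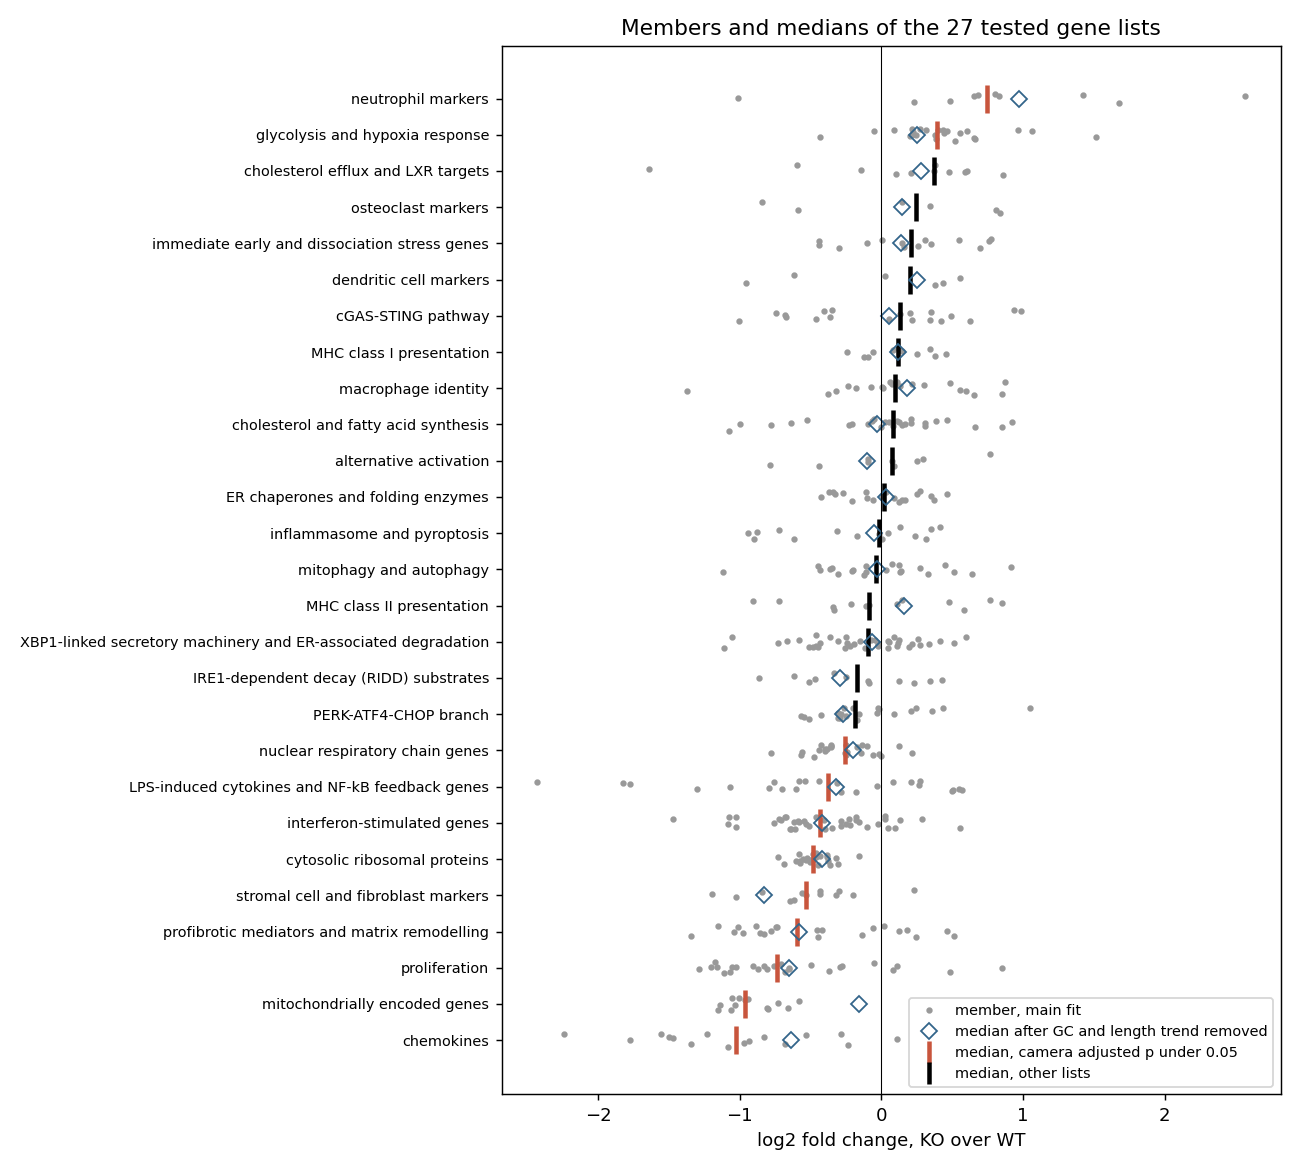
Rows are the 27 tested gene lists, the horizontal axis is the log2 fold change of KO over WT, grey points are member genes, vertical ticks are list medians (red where camera's adjusted p is under 0.05) and open diamonds are medians after removal of the GC and length trend. Chemokines have the lowest median, -1.03, and mitochondrially encoded genes move most with the removal, from -0.96 to -0.15.

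In all, camera called 11 of the 27 tested lists, 2 higher and 9 lower in KO. With an estimated correlation camera called 0 lists, 7 had an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 25. For profibrotic genes the estimated correlation was -0.023, below the preset value, yet camera's unadjusted p rose from 6.91e-04 to 0.020. A higher correlation does not account for that rise. For the other called lists the estimate lay above the preset value, up to 0.271 for ribosomal protein genes. A call lost with an estimated correlation thus does not by itself show correlated members. With that setting the lowest adjusted p over all lists was 0.146, which ribosomal protein genes also had although all 25 fell. Such a lost call is therefore not evidence that a list was unchanged. The sign of the median, the mean and the test differed for some uncalled lists. For ER chaperones the median was 0.02 (0.13 with library totals as the scaling) with camera's direction lower, and for MHC class II genes the median was -0.09 (0.02 with library totals as the scaling, 0.16 after removal of the trend) and the mean 0.02. For dendritic cell markers the median was 0.20 (0.32 with library totals as the scaling) and the mean -0.03.

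Log2 fold changes increased with the GC content and the length of genes. Across genes, which are not independent replicates, Spearman's rho was 0.32 for GC content and 0.27 for length, and the 2 properties explained 22.6% of the variance. The median log2 fold change was -0.27 in the 10% of genes with the lowest GC content and 0.22 in the 10% with the highest. WT and KO libraries fell on opposite sides, with slopes per 10 points of GC content of -0.13, -0.14 and -0.22 in WT replicates 1 to 3 and 0.17, 0.18 and 0.14 in KO replicates 1 to 3. The labels give no library batch, and the trend and the genotype cannot be told apart. With the trend removed, 7251 genes were called, 3553 higher and 3698 lower, and Xbp1 had a log2 fold change of -0.59.

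**Figure D3:**
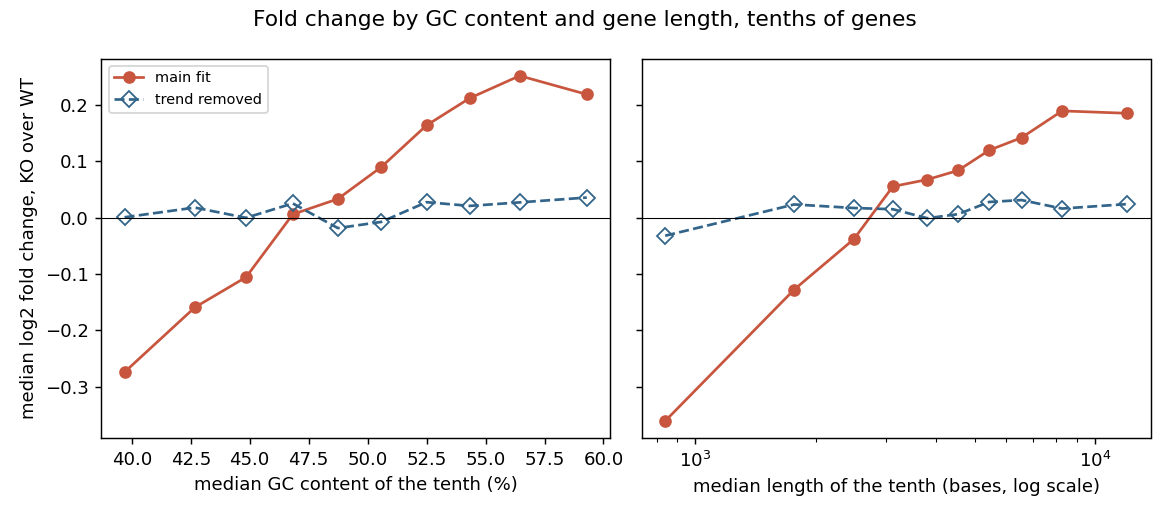
Median log2 fold change of KO over WT (vertical axis) for 10 equal groups of genes ordered by GC content in percent (left) and by length in bases on a log axis (right), in the uncorrected fit (filled points) and after removal of the trend (open diamonds). The uncorrected medians run from -0.27 to 0.25 over GC content and from -0.36 to 0.19 over length.

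At an adjusted p under 0.05, 3681 genes were higher and 3387 lower in KO in the authors' deposited table. Of these, 6994 were among the genes tested here, 6992 were called in the same direction and 0 had the opposite sign.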

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

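Alternatives added after the data were seen are the removal of the GC and length trend, limma on FPKM and leaving out genes with near-identical copies. The count of 8019 called genes was 898 (377 higher, 521 lower) when a 2-fold change was also required. Under the other settings it lay between 6204 (mean of at least 5 CPM, which tests fewer genes) and 8140 (no expression filter), with 7081 for DESeq2, 7251 without the GC and length trend, 6858 without genes with copies and 7387 to 7671 when a library was left out. Xbp1 stayed lower in every setting, between -0.59 and -0.32. The 11 lists called by camera became 0 with an estimated correlation and 25 with fry, and were 11 to 13 otherwise. Same-numbered libraries of the genotypes deviated with correlations across genes of -0.03, 0.08 and 0.02, so the numbers were not taken to pair them, and a replicate block gave 8013 genes and 11 lists. DESeq2 did not call Srp54b, Cd4 or Dcstamp. On log2(FPKM + 1) the changes of low genes were smaller, since that scale understates them. Values near 0 changed sign, and the cause was not tested. Nlrp3 was -0.026 at 5 CPM, -0.0061 with DESeq2 factors, -0.15 without the trend, -0.036 without copies and -0.013 to 0.012 when a library was left out. Mean changes of uncalled lists, taken relative to the mean of all tested genes, also changed sign, and not all of these values were near 0. At 5 CPM ER chaperones were -0.032, mitophagy -0.0047, cholesterol synthesis -0.018 and MHC class II -0.14. With no filter alternative activation was -0.39 and mitophagy -0.0050. Without the trend cGAS-STING was -0.074, alternative activation -0.056, mitophagy -0.045, cholesterol synthesis -0.093 and dendritic markers 0.0016. Without copies ER chaperones were -0.012, alternative activation -0.015 and mitophagy -0.040. On FPKM MHC class II was -0.051 and dendritic markers 0.0075. With a library left out, ranges were -0.0013 to 0.031 for cGAS-STING, -0.080 to 0.044 for alternative activation, -0.0071 to 0.016 for mitophagy, -0.0023 to 0.046 for MHC class II and -0.046 to 0.16 for dendritic markers. Changing the pseudocount was not run, since the test on counts has none. Depth limits Elane, Prtn3 and Csf2, with 8, 18 and 54 counts over the WT libraries.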

Other observations

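Chosen only after the results were seen were the removal of the GC and length trend, the tests of transcription factor families, the comparison with stromal markers, the share of Lyz1, and the summed reads of Lyz1 and Lyz2 and of Gapdh and its copies. Proliferation genes were lower in KO. Of 26 measured members 17 fell and 2 rose, also when adjusted over the list alone, with a median log2 fold change of -0.73. Birc5, which encodes survivin, fell from 6.82 ± 0.176 to 2.95 ± 0.122 CPM and Hmmr from 1.72 ± 0.143 to 0.688 ± 0.242 CPM. The list was called lower by camera (adjusted p = 2.36e-04), but not with an estimated correlation (adjusted p = 0.146). Immediate early and heat shock genes included 8 that rose and 3 that fell of 14, also adjusted over the list alone (camera adjusted p = 0.159), with Jun at 0.77 and Fos at 0.76.

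Lipid and antigen presentation lists were not called in the main test. Cholesterol and fatty acid synthesis had 8 that rose and 5 that fell of 27 (camera adjusted p = 0.655), but 6 that rose and 10 that fell after removal of the trend, with Acly, ATP citrate lyase, at 0.92 and Idi1, which has copies, at -1.07. Among 11 cholesterol efflux and LXR targets 7 rose and 3 fell (camera adjusted p = 0.159), with the cholesterol exporter gene Abca1 at 0.86 and the fatty acid binding protein gene Fabp4 at -1.64. MHC class II presentation had 6 that rose and 4 that fell of 13 (camera adjusted p = 0.918), with the costimulatory receptor gene Cd40 at -0.91 and H2-Ob at 0.85. MHC class I presentation had 6 that rose and 3 that fell of 11 (camera adjusted p = 0.225), with H2-K1 at 0.46 and H2-D1 at 0.38, the latter at 0.23 after removal of the trend. With library totals as the scaling camera called the class I list higher (adjusted p = 0.0474), but not with an estimated correlation (adjusted p = 0.214). Dendritic cell markers had 2 that rose and 2 that fell of 6 (camera adjusted p = 0.904), with Xcr1 at -0.96 and Tcf4 at -0.62. Osteoclast markers had 4 that rose and 2 that fell of 6 (camera adjusted p = 0.662), with Atp6v0d2 at -0.84 (-0.48 after removal of the trend) and Dcstamp at 0.83, the latter losing its call without WT replicate 2, WT replicate 3 or any KO replicate (0.75 to 0.87). In these 6 lists the counts adjusted over the list alone were the same. Of the transcription factor families, camera called RHD, the Rel family, higher (8 of 10 members rose, adjusted p = 0.0437), but not with an estimated correlation (adjusted p = 0.414) or after removal of the trend (adjusted p = 0.182). Processed pseudogenes had a median of -0.40 over 678 tested, and -0.01 after removal of the trend.

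Chemokines, interferon-stimulated genes and LPS cytokines fell together in KO. The median of their 79 tested members was -0.53, and -0.42 (95% bootstrap interval over genes -0.49 to -0.31) after removal of the GC and length trend. That interval is likely too narrow, since the estimated correlation was 0.241 for chemokines and 0.228 for interferon-stimulated genes (0.0589 for LPS cytokines). After the removal, 15 of 16 chemokines, 34 of 40 interferon-stimulated genes and 16 of 24 LPS cytokines were called lower. Called higher were 1, 2 and 5 of them. These counts argue against that trend, as fitted to the deposited gene lengths, as the whole cause. Fewer stromal cells in the KO cultures stays open as a cause, since a comparison of list medians cannot decide it. The chemokine median minus the stromal marker median was 0.19 (-0.43 to 0.57) after the removal. Over all 79 members the difference was 0.40 (0.10 to 0.63), with the stromal median the lower. Both intervals treat genes as independent, and list medians do not show which cells made a transcript. After the removal 1 of the 16 chemokines, Ccl7 at -1.61, lay below the lowest stromal marker, at -1.32. The stromal markers Acta2 and Sparc had 347 and 82.7 CPM in WT, and macrophages also transcribe some genes of this list. Sparc belongs to the list of IRE1-dependent decay substrates too. The stromal markers Lum and Lepr averaged 0.0883 and 0.0467 CPM and did not pass the filter. An effect of the Xbp1 deletion on inflammatory transcription also stays open, and was not tested apart from stromal content.

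Ribosomal protein and mitochondrially encoded transcripts were lower in KO. For ribosomal protein genes the median of -0.49 became -0.42 (95% bootstrap interval over genes -0.49 to -0.33) after removal of the trend. The removal used the deposited gene length, with a median of 1830 bases for this list, which can differ from that of the sequenced mRNA. Near-identical copies also exist for 21 of the 25 genes. All 25 genes were still called lower after the removal, which argues against the trend, as fitted to the deposited lengths, as the whole cause. An effect of GC content or length that the fit misses stays open, for the reasons above. For mitochondrially encoded genes the median of -0.96 became -0.15 (-0.23 to 0.03), so the trend of the libraries may account for most of that fall. Whether the trend comes from library preparation or from the cells cannot be told apart, because it separates the genotypes.

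Lyz2 was lower and its neighbour Lyz1 higher in KO. Lyz1 held between 0.0268% and 0.0271% of the reads of both genes in WT libraries and between 0.368% and 0.394% in KO libraries. The summed reads had a log2 fold change of -1.37 (95% interval -1.41 to -1.32), so the fall of Lyz2 is not made up by reads counted for Lyz1, and Lyz2 alone was at -1.09 (-1.12 to -1.06) after removal of the trend. The rise of Lyz1 stays open. Its lowest KO share was 13.6 times its highest WT share, which a rise of the gene would give. Lyz2 reads counted for Lyz1 would give it too only if their part of the Lyz2 reads grew in KO, since a constant part leaves the share unchanged. A candidate explanation is a Cre driver inserted at Lyz2, a common way to delete floxed genes in myeloid cells, but the labels do not name the driver and no test here bears on it.

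Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many called genes as the split by genotype, which was that split itself, with 8019 genes against a highest other count of 1. For gene lists 1 split also reached the real count, 11 lists against a highest other count of 9, and the other splits called at least 5 lists each with camera's preset correlation. Every other split mixed the genotypes, so a genotype difference widened the spread within its groups and left few genes to call. Those splits also kept unequal numbers of each genotype, so their list counts are not a rate without a difference. With 10 splits a share under 0.05 cannot be reached.

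Gapdh had 10.6, 282 and 10.8 CPM in WT replicates 1 to 3 and 231, 310 and 327 CPM in KO replicates 1 to 3, and was named after its values were seen. It belongs to the glycolysis and hypoxia list and has 71 near-identical copies. The summed counts of the gene and its copies were 88.4, 363 and 85.7 CPM in WT and 327, 421 and 430 CPM in KO. Their log2 fold change was 1.13 (SE 0.363, edgeR adjusted p = 0.0126), although WT replicate 2 lay within the range of the KO libraries. Summing the copies thus did not remove the difference between WT replicates, and these counts do not settle whether Gapdh changed.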
